A study of Mus musculus with 4 samples.

How the data were processed

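RNA was sequenced from 4 samples of mouse primary cells of strain C57BL/6NJ that the labels call T-helper 2 cells. T-helper 2 (Th2) cells are the CD4 T cells that make interleukins 4, 5 and 13. The labels call the assay total RNA-seq, while the library protocol they link to is named for poly(A)-selected RNA. They also link a protocol for T cell differentiation, whose text was not used here. The samples are numbered as biological replicates 1 to 4 and share 1 donor identifier. Whether the cells came from separate mice is not stated. P-values taken over the libraries therefore measure the spread between these 4 samples, whatever its source. Those for list spread and for correlation over gene pairs were taken over genes or pairs and do not measure it. Counts at genes of the sex chromosomes, given below, bear on whether the mice were separate. The labels give the sex as not collected.

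The deposited values are raw counts of fragments per gene, 1 table per sample. Per the file headers, the authors counted read pairs with featureCounts 1.4.6-p4 over the exons of GENCODE mouse release 13, on the mm10 build, after alignment with STAR. The strand setting was 1, which assigns a fragment to a gene on the strand of its first read, and both ends had to be aligned. The other deposited column used was the exon length of each gene in bases. The counts were not normalised by the authors, per the file headers. The headers name the samples as 0 hours of a Th1 and Th2 time course. The labels give no time, so whether the cells had begun to differentiate is not known. Library kit and trimming are not given in the sources used here. Separate signal tracks for the plus and the minus strand are listed with each sample and were not analysed here.

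All 50600 genes of the tables were read with pandas 2.3.3 in Python 3.11.15. Symbols were matched by gene identifier without version for 50376 of them, and 224 kept their identifier. Gene types came from GENCODE mouse release 21. Totals ranged from 1452053 to 2351916 counts per library. The upper limit that a count of 0 allows, 3 counts, corresponded to 1.28 to 2.07 CPM, the count scaled by the library total. Intervals and limits cover counting error only, because reads without molecular identifiers are not independent molecules. TPM was computed here from the deposited counts and exon lengths, and log2 values used a pseudocount of 0.1 TPM. A gene of a list was called detected at a mean of 1 TPM or more, which refers to fragments on its annotated strand. No library was a copy of another, since a chi-square comparison of counts over genes gave 7.35 to 30.9 per degree of freedom for the 6 pairs.

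Each gene was placed by its exons relative to the genes annotated on the opposite strand, with bedtools 2.31.1. It overlapped an exon of such a gene, lay within its introns, lay within 5 kb of it, or had none within 5 kb. This grouping was chosen after the counts had been seen. The opposite gene of a list gene was a gene not annotated as protein-coding, with an exon overlap of at least 100 bases that was its largest with any gene of the other strand. Count densities were compared over 193 pairs in which a protein-coding gene covered at least 80% of the exons of such an opposite gene and the pair had a mean count of at least 20.

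There was 1 group, so gene lists and genes were compared within each library. Fixed before the data were examined were 16 programme lists, 8 lists of markers of other cell types, 14 ratios of gene pairs and the rule for naming genes. The rule took the first 2 members of each programme list, its 4 members with the highest mean TPM and its 2 with the lowest. It also took the 2 highest members of each marker list, the 10 genes with the highest TPM outside the mitochondrial genome, the 10 most variable loci and both genes of each ratio. Some genes that the rule took are not described. Other genes named below were chosen after their values were seen. These are the opposite genes and the list genes they belong to, mitochondrial genes, genes of the sex chromosomes, Actb, and marker genes given at 0. List levels were means of log2(TPM + 0.1) per library. Differences and ratios were tested with an exact two-sided sign-flip permutation over the 4 libraries, in which 2 of 16 sign patterns are the most extreme. Ratios were adjusted by the Benjamini-Hochberg method over all 14. A fold against a gene at 0 in all libraries was taken against 3 counts over the group. Other folds used counts summed over libraries, per exon length, with an exact (Clopper-Pearson) 95% interval.

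Spread between libraries was estimated with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with filterByExpr, TMM factors and an intercept-only design. A gene counted as more variable than the trend when its quasi-dispersion exceeded the fitted prior by an upper-tail F test at a Benjamini-Hochberg adjusted p of 0.05. The planned measure of list spread, tagwise over trended dispersion, took 1 value for all genes because the prior degrees of freedom were infinite. Quasi-dispersion over its prior, also fixed in advance, was used in its place against 10000 random lists matched on mean expression. The test of variable genes was tested on simulated data for the 5755 genes. Of 200 genes with a dispersion raised 10-fold, 152 passed the filter and 47 of these were called. With a 30-fold rise 94 passed and 54 were called, and either run gave 0 false calls. All other simulated genes shared the common dispersion. The 0 false calls therefore do not show how the test behaves where dispersion differs between genes, as it may in these data. Alternatives tried were other pseudocounts, FPKM, TMM-scaled CPM, DESeq2 1.42.0 size factors and dispersions, other filters and the omission of each replicate. Ribosomal protein genes were taken by symbol, without the Rps6k kinases. The design had foreseen estimated counts and TPM with intervals. The tables hold raw counts, so alternatives built on such intervals or on posterior means were not run.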

Results

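Gene counts were analysed for 4 libraries of cells labelled as mouse T-helper 2 cells, biological replicates 1 to 4 of 1 group. The libraries held 2131288, 2351916, 1923157 and 1452053 counts in that order, over 50600 annotated genes. Between 12270 and 14884 genes had at least 1 count per library, and 33594 genes had none in any. A TPM of 1 or more was reached in every library by 7279 genes, of which 5118 were protein-coding.

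Most counts lay in genes that overlap another gene on the opposite DNA strand. The 8189 genes with such an exon overlap were 16.2% of all genes and 26.2% of exon length, and held 88.6% ± 1.06 of the counts (SD, n = 4). The 27571 genes with no opposite-strand gene within 5 kb held 3.64% ± 0.502. All 40 genes with the most counts had an opposite-strand exon overlap. Without the ribosomal RNA locus CT010467.1 and mt-Nd6 the share was 87.1% ± 1.60, and among protein-coding genes it was 81.4% ± 2.29.

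**Figure D1:**
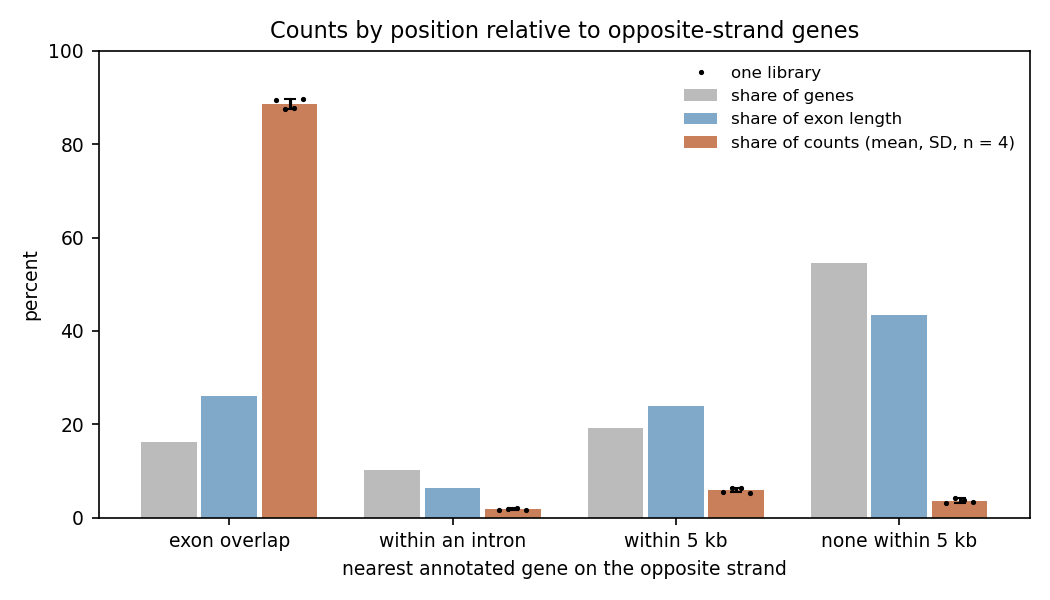
Share of annotated genes, of exon length and of counts (percent, bars) by position relative to genes annotated on the opposite strand; count bars are means of 4 libraries with SD, and points are libraries. Genes with an opposite-strand exon overlap were 16.2% of genes and held 88.6% of counts.

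In the mitochondrial genome, mt-Nd6 is the one mRNA annotated on the minus strand. On mm10, mt-Nd6 (bases 13552 to 14070) held 31257 ± 4872 counts (SD, n = 4). The other 12 mRNAs together held 2348 ± 699, so that mt-Nd6 exceeded their sum 14.2 ± 5.16-fold. The neighbouring mt-Nd5 had 0.331% ± 0.0865 of the count density of mt-Nd6. No count was assigned in any library to mt-Co2, mt-Atp8, mt-Atp6, mt-Co3 or mt-Nd4l, and mt-Nd3 had 2 counts, in replicate 3. These genes lie together, between mt-Co1 at 588 and mt-Nd4 at 157 counts per kb on the same strand. They are among the 12 mRNAs, and the cause of their low counts was not tested.

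The 10 genes with the highest TPM outside the mitochondrial genome all overlapped an exon of an opposite-strand gene. Gm15441, opposite to Txnip, a regulator of glucose uptake, had 10467.4 ± 2030 CPM against 60.5 ± 20.2 for Txnip (SD, n = 4). Other genes of highest TPM were Gm22953 opposite to Serf2, Gm37376 and ENSMUSG00000092267 opposite to the nuclear RNA Malat1, Gm20490 opposite to Rbm38, Gm11175 opposite to Jund and Gm20721 opposite to Gnas. Actb, the cytoskeletal actin, has no opposite-strand gene within 5 kb and had 197 ± 43.1 CPM. Over 193 covered pairs, the protein-coding gene had a median 0.417% ± 0.0997 of the count density of its opposite gene, which was denser in 173 pairs. A gene's count was therefore not read as its transcript level. It is the number of fragments assigned to the annotated strand of the gene, and exon overlaps are named for list genes given with a TPM.

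Cd3e encodes a chain of the T cell receptor complex (ENSMUSG00000032093.7, chromosome 9, 44998740 to 45009627). Its opposite gene Gm48719 had 2779.6 ± 205 CPM, against 27.7 ± 9.03 for Cd3e (SD, n = 4). The opposite gene of Skap1, an adaptor of receptor signalling, had 1776 ± 177 CPM. Among naive and memory genes, the opposite gene of Lef1, a transcription factor (chromosome 3, 131110471 to 131224356), had 1703 ± 123 CPM, that of Foxo1 880.5 ± 49.4 and that of Bach2 729.7 ± 81.0. Opposite to Satb1, a chromatin organiser of the same list, were 81.7 ± 16.1 CPM, fewer than the 130 ± 26.2 of Satb1 itself.

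Opposite genes of helper lineage genes ranged widely. In the Th2 list, 679 ± 78.4 CPM lay opposite to the interleukin-4 receptor gene Il4ra (SD, n = 4). Gm13256, opposite to Gata3, the main Th2 transcription factor (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034), had 160.5 ± 30.2 CPM. The opposite genes of Maf and Gfi1, which also act in Th2 cells, had 22.7 ± 2.82 and 18.3 ± 4.27 CPM. Gm12214, opposite to Il5, had 1 count over the 4 libraries, and that of Bhlhe41 had none. In the Treg list, 522 ± 79.8 CPM lay opposite to Tnfrsf18, the GITR receptor, and 2.12 ± 2.21 opposite to Ikzf2. Opposite to Eomes of the Th1 list were 11.6 ± 7.48 CPM, and opposite to Il21 were 10 counts in all. Opposite to Cd22 of B cells were 10 counts in all. Opposite to Mpo of granulocytes and Pax5 of B cells no count was found, which allows up to 1.28 to 2.07 CPM per library. Of the 35 list genes with such an opposite gene, 26 had fewer counts than it. Differences between lists were not tested.

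**Figure D2:**
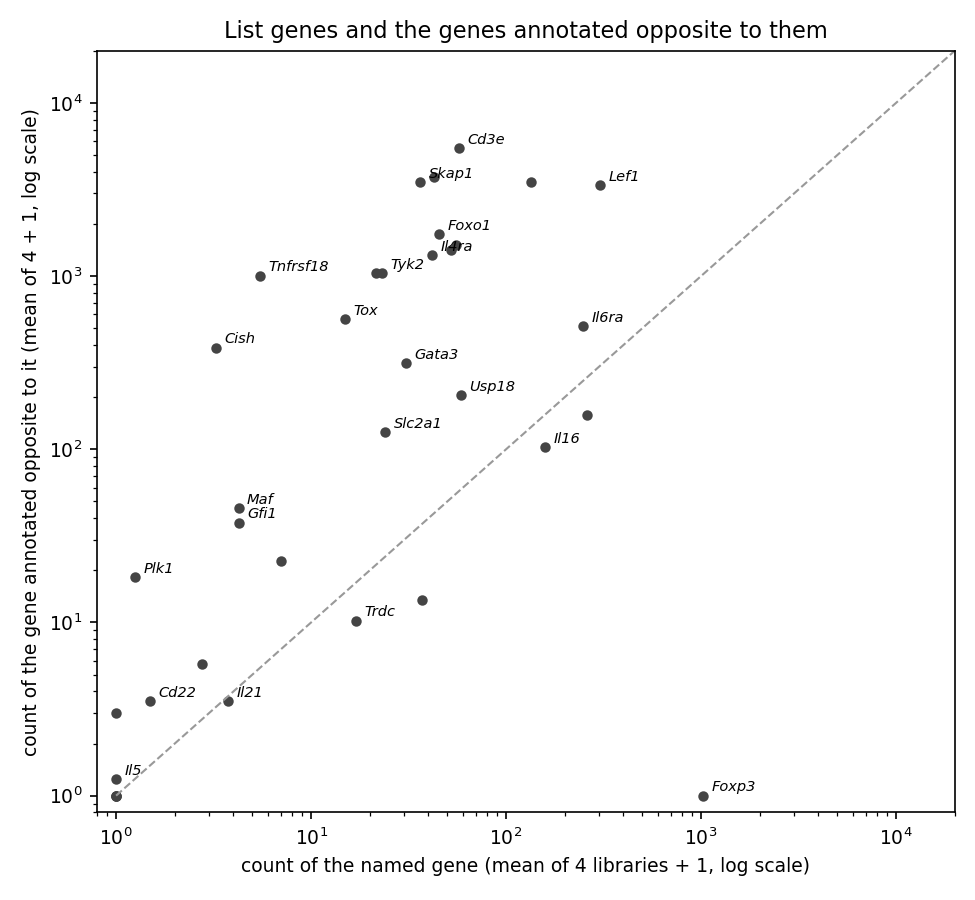
Mean count of each list gene (x axis, log scale, 1 added) against that of the gene annotated opposite to it (y axis, log scale, 1 added), means of 4 libraries; labels mark genes named in the text where they did not overlap. The dashed line marks equal counts, and 26 of the 35 genes lie above it.

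On their own annotated strand, 8 of 24 Th2 list members reached a mean of 1 TPM, 8 had no count in any library and 13 had at most 3 counts in all. Il5 and Il13, cytokines that define the lineage, had 0 counts in every library. Il4 (chromosome 11, 53602982 to 53618669) had 14, 12, 25 and 2 counts, or 7.96 ± 5.76 TPM (SD, n = 4). Gata3 had 5.87 ± 2.08 TPM. The highest members were Il17rb, a receptor chain for interleukin 25, at 17.3 ± 1.94 TPM, Stat6, which signals from the interleukin-4 receptor, at 11.6 ± 2.11, and Ptgdr2, a prostaglandin receptor, at 9.97 ± 1.43. Gata3, Stat6 and Ptgdr2 overlap exons of opposite-strand genes.

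The Th2 list stood above the Th1 and Th17 lists and below the Treg and Tfh lists in each of the 4 libraries. The comparison asks whether fragments on the annotated strand of Th2 list genes exceed those of the other helper lists. The file headers place these cells at 0 hours of a Th1 and Th2 time course. Counts were not read as transcript levels, so the order of the lists does not rank the lineages. Opposite-strand exons are overlapped by 9 of 24 Th2, 2 of 20 Th1, 4 of 13 Th17, 4 of 16 Treg and 4 of 12 Tfh members. The Th2 level was higher than the Th1 level by 0.44 ± 0.13 on the log2 scale and higher than the Th17 level by 1.08 ± 0.34 (SD, n = 4). It differed from the Treg level by -0.66 ± 0.17 and from the Tfh level by -1.14 ± 0.36. Each of the 4 tests gave p = 0.12 by the exact sign-flip permutation, the smallest that 4 libraries allow, so none could pass 0.05. The sizes depended on the pseudocount. With 1 and with 0.01 TPM added, they were 0.25 and 0.67 for Th1, 0.42 and 1.87 for Th17, -0.33 and -1.19 for Treg, and -0.64 and -1.65 for Tfh. With list medians they were 0.71, 0.81, -1.80 and -2.13. In settings chosen after the counts were seen, they were 0.21 ± 0.13, 0.87 ± 0.38, -0.75 ± 0.27 and -1.03 ± 0.47 over members without opposite-strand exon overlap. Over members with no opposite-strand gene within 5 kb they were -0.038 ± 0.246, 0.98 ± 0.32, -1.23 ± 0.28 and -1.38 ± 0.62, so the Th1 difference was lost. Over members with a TPM of at least 1 in at least 1 library, the differences were 1.68 ± 0.24 for Th1, 0.62 ± 0.93 for Th17, -0.13 ± 0.27 for Treg and -0.53 ± 0.43 for Tfh. Their exact sign-flip permutation p were 0.12, 0.25, 0.375 and 0.25, so the last 3 did not keep 1 sign in all libraries. With list medians, the Th1 and Th17 differences had p = 0.25 by the same exact permutation and did not keep it either.

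Genes of the other helper lineages differed among themselves. Tbx21 and Ifng of Th1 cells, Il17a of Th17 cells and the chemokine receptor genes Cxcr3 and Ccr6 had 0 counts in all 4 libraries. Foxp3, the regulator of regulatory T cells (ENSMUSG00000039521.12, chromosome X, 7579676 to 7595243), had 1127, 1144, 1065 and 768 counts, or 199 ± 4.99 TPM (SD, n = 4). Foxp3 overlaps exons of Ccdc22 on the opposite strand, so these counts cannot be assigned to Foxp3 transcripts. In the Treg list Izumo1r had 17.0 ± 3.36 TPM, Itgae 5.73 ± 2.02 and Gpr83 2.55 ± 0.964, while Il2ra, an interleukin-2 receptor chain, had 0.324 ± 0.193 and Klrg1 and Entpd1 none. In the Th1 list Il12rb2 had 12.3 ± 3.16 TPM, Runx3 6.14 ± 1.86 and Il18r1 3.67 ± 1.65. In the Th17 list 8 of 13 members had no count, Rora, which overlaps Gm15511, had 1, and the members detected were Cxcr6 at 20.965 ± 1.56 TPM and Stat3 at 5.72 ± 0.919. In the Tfh list Cxcr5, a follicle-homing receptor, had 22.6 ± 3.82 TPM, Il6ra 21.8 ± 8.44, Cd40lg 13.6 ± 1.84 and Btla 7.75 ± 4.75, whereas Bcl6 had 0.505 ± 0.362 and Ascl2 and Tox2 had none. Il12rb2, Stat3, Cxcr5, Il6ra and Bcl6 overlap opposite-strand exons, and Cxcr6 lies within an intron of an opposite-strand gene.

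Ratios between lineage genes followed these counts. They compared fragments assigned to the annotated strand of each gene, not transcript levels. Gata3, Bcl6, Il21 and Stat6 overlap opposite-strand exons. Gata3 was at least 24.6-fold higher than Tbx21, and Il4 was at least 18.6-fold higher than Ifng. Gata3 was 10.5-fold higher than Bcl6 (95% interval 6.41 to 18.0), Il4 20.7-fold higher than Il21 (10.7 to 43.8) and Stat6 10.7-fold higher than Stat4 (6.91 to 17.3). Gata3 was 34.7-fold lower than Foxp3 (28.9 to 42.0), with the overlap at Foxp3 given above. Il1rl1, the interleukin-33 receptor, had 2 counts in all and was 67.3-fold lower than Il18r1 (18.1 to 564) and 11.1-fold lower than Il23r (2.21 to 107). The 8 counts of Il23r were all in replicate 4, and the mean log2 ratio of Il1rl1 to Il23r changed from -0.88 to 0.53 without it. In replicate 4 Il4 had 2 counts and Il21 had 5. Without that library the mean log2 ratio of Il4 to Il21 moved from 3.74 to 4.74 and that of Il4 to Ifng from 5.96 to 6.56. Because Ifng had 0 counts, the size of the Il4 to Ifng ratio was set by the pseudocount and is no measured fold. It was 2.89 with 1 and 9.26 with 0.01 TPM added. With TMM-scaled CPM, which is not divided by length, Il4 over Il21 was 1.93 ± 2.26 (exact sign-flip permutation p = 0.25). The mean log2 ratio of Il1rl1 to Il18r1 moved from -4.73 to -5.36 without replicate 1, which held both Il1rl1 counts. With 1 and with 0.01 TPM added, that ratio was -2.09 and -7.31. Of the 9 ratios with a fold, 1 of which is not described, 8 had 1 sign in all 4 libraries and p = 0.12 by the exact sign-flip permutation (adjusted p = 0.219), and Il1rl1 over Il23r had p = 1. For 5 of the 14 planned ratios both genes had at most 3 counts and no fold is given: Il5 over Ifng, Il13 over Ifng, Il13 over Il17a, Ccr4 over Cxcr3 and Ccr8 over Ccr6.

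Genes of T cell identity all had fragments assigned to their annotated strand. All 21 members of that list reached a mean of 1 TPM, at a level of 4.29 ± 0.28 on the log2(TPM + 0.1) scale (SD, n = 4). The receptor constant genes Trac, Trbc2 and Trbc1 had 66.0 ± 13.5, 54.8 ± 10.1 and 54.5 ± 16.04 TPM, and Cd3d had 40.9 ± 9.13. Cd247, which overlaps exons of Pou2f1, had 174 ± 31.2. The lowest members were Txk at 1.75 ± 0.773 and Skap1 at 3.65 ± 0.341. Of the 21 members, 17 have no opposite-strand exon overlap, but their counts were not read as transcript levels either.

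Genes of naive and memory T cells stood near that level. Of 12 members 11 were detected, at a level of 3.93 ± 0.40 (SD, n = 4). Ccr7, a homing receptor of naive cells, had 32.5 ± 6.35 TPM, and Il7r, the interleukin-7 receptor, had 37.4 ± 10.8. Ccr7 and Il7r have no opposite-strand gene within 5 kb. Cd27 and Tcf7 had 130 ± 24.3 and 99.1 ± 26.5 TPM and lie within introns of opposite-strand genes. Cd44, an adhesion receptor that marks experienced T cells, had 4, 16, 2 and 0 counts, or 0.557 ± 0.709 TPM, and Bach2 had 3.84 ± 1.64.

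Activation genes were lower, at a level of 0.96 ± 0.31 (SD, n = 4) with 16 of 23 members detected. Il2ra had 5, 2, 2 and 1 counts and Il2 had 1 in all. Tnfrsf4, the OX40 receptor, had 1.93 ± 2.83 TPM, with 8 of its 11 counts in replicate 4. The highest members were Junb at 64.6 ± 8.53 TPM, Nfkbia at 14.6 ± 4.37, Cd40lg at 13.6 ± 1.84 and Jun at 13.4 ± 2.52, of which Junb and Jun overlap opposite-strand exons. Inhibitory receptors had a level of -0.23 ± 0.77, and 5 of 10 were detected. Btla, Cd160 and Vsir had 5.43 to 7.75 TPM, Tox 1.31 ± 0.922, Ctla4 1.08 ± 1.37 and Pdcd1 0.595 ± 0.447, and Havcr2 and Tigit had 1 count each. Cd160 and Tox overlap opposite-strand exons, and Vsir and Il2 lie within opposite introns.

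**Figure D3:**
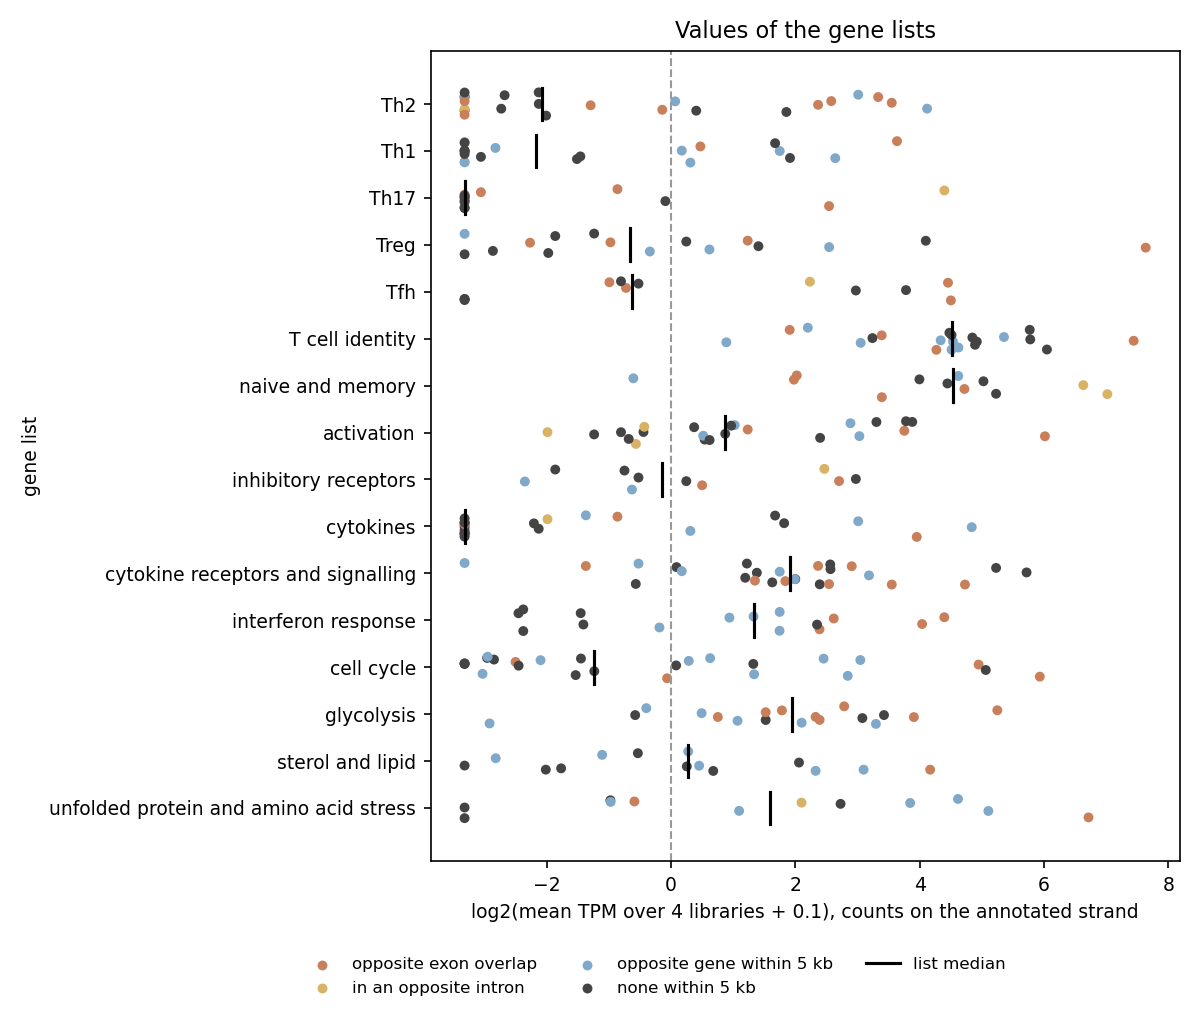
Each point is a gene of a programme list, at log2 of its mean TPM over 4 libraries plus 0.1 (x axis), coloured by its position relative to opposite-strand genes, with list medians as black bars. The identity and naive lists lie to the right, with levels of 4.29 and 3.93.

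Cytokine genes were mostly without counts. Of 24 members, 13 had 0 counts in every library and 6 were detected. The highest were Ltb, a lymphotoxin chain, at 28.5 ± 9.50 TPM and Il16, which overlaps exons of Stard5, at 15.4 ± 2.61 (SD, n = 4). Tgfb1 had 3.43 ± 1.05 TPM and Il3 none. Cytokine receptors and their signalling genes were detected in 21 of 26 cases. Socs3, a feedback inhibitor, had 52.6 ± 7.998 TPM, Jak1, which overlaps exons of Raver2, 26.4 ± 7.77 and Il2rg, the common gamma chain, 8.99 ± 4.73. Il2rb had 0.962 ± 0.302 TPM, Cish, which overlaps exons of Gm17041, 0.287 ± 0.317 and Socs2 none.

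Among cell cycle genes 10 of 25 were detected, and 9 had at most 3 counts in all. Ccnb1 and Ccnb2, cyclins of mitosis, had none and Top2a had 0.133 ± 0.158 TPM (SD, n = 4). Mki67 had 5.38 ± 0.818 TPM. The highest members were Ccna2 at 61.0 ± 4.69, Ccne1 at 33.3 ± 2.19, Mcm7 at 30.8 ± 3.24 and Aurka at 8.15 ± 3.48. Ccna2 and Mcm7 overlap exons of Exosc9 and Ap4m1, while Ccne1 has no opposite-strand gene within 5 kb.

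Metabolic, stress and interferon genes were intermediate. Glycolysis had 15 of 18 members detected at a level of 1.63 ± 0.26 (SD, n = 4). Pfkp had 37.9 ± 6.23 TPM, Gapdh 14.9 ± 2.32, Ldha 10.6 ± 2.22 and Slc16a3 9.72 ± 2.404, while Slc2a1 had 5.14 ± 1.11, Slc2a3 0.570 ± 0.374 and Hk2 had 1 count. Sterol and lipid genes had 8 of 14 detected, with Fdft1 at 17.9 ± 3.02, Sqle at 8.46 ± 2.64, Srebf2 at 4.91 ± 1.58, Cpt1a at 4.06 ± 0.264, Hmgcs1 at 1.27 ± 1.12 and Scd1 at 0. Among genes of the unfolded protein and amino acid stress responses 7 of 12 were detected. Ddit3, which overlaps Mars, had 105 ± 22.9 TPM, Calr 34.3 ± 9.42, Hspa5 24.4 ± 5.82, Atf4 14.3 ± 2.20 and Xbp1 2.04 ± 1.32, and Asns and Chac1 had none. Of 15 interferon response genes 9 were detected. Irf1 had 20.96 ± 4.73 TPM, Usp18 16.3 ± 3.78, Irf7 6.04 ± 0.807 and Gbp2 5.14 ± 1.77, all with opposite-strand exon overlap, whereas Isg15 had 2.41 ± 2.30 and Ifit1 1.82 ± 1.36. The lowest members, Ifi44, Oas1a and Acaca, had 3, 1 and 4 counts in all. Pfkp, Gapdh, Slc2a1 and Fdft1 also overlap opposite-strand exons.

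Markers of other cell types were mostly at 0. Of 85 such genes, 57 had no count in any library, against 33594 of all 50600 genes (66.4%). Among the 21764 protein-coding genes, 12055 had a count. Of the 85 markers 17 were detected, 14 of them without opposite-strand exon overlap. The highest were Csf1r of macrophages at 107 ± 10.7 TPM (SD, n = 4), which overlaps Hmgxb3, Cpa3 of mast cells at 42.4 ± 11.9 and Cd79a of B cells at 39.0 ± 3.91. Cpa3 and Cd79a have no opposite-strand gene within 5 kb. Ighm of B cells had 22.7 ± 7.53 TPM, Tyrobp of myeloid cells 14.1 ± 4.89, Alas2 of erythroid cells 12.1 ± 5.07 and the endothelial marker Pecam1 7.73 ± 2.15. Klrk1 of cytotoxic cells had 4.67 ± 1.56 TPM, Cd8b1 1.34 ± 1.56 and Trdc of gamma-delta T cells 3.10 ± 2.52. Alas2 and Trdc overlap exons of Apex2 and Trdv5. Hdc of basophils had 3.66 ± 0.883 TPM, Klf1 5.01 ± 2.80 and Epx of eosinophils 1.78 ± 0.746. Sox13 had 17 counts in all, Epcam 2 and Siglecf none. Lyz2 of macrophages and the collagen gene Col1a1 had 0 counts in all libraries.

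Classes of RNA were measured under the same limit. Ribosomal protein genes held 1.30% ± 0.149 of TPM and mitochondrial genes 5.80% ± 0.456 (SD, n = 4), of which 1.13% ± 0.0863 came from genes other than mt-Nd6. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, held 0.00826% ± 0.00201. As shares of counts, ribosomal protein genes held 1.04% ± 0.103, mitochondrial genes 1.78% ± 0.179 and these histone genes 0.00382% ± 0.000877. The ribosomal RNA locus CT010467.1 on chromosome 17 (39846353 to 39848827, minus strand) held 6.90%, 16.8%, 3.47% and 12.6% of the counts of replicates 1 to 4.

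Pearson correlations of log2(TPM + 1) across genes ranged from 0.940 to 0.956 over the 6 pairs of libraries, and genes are not independent replicates. The biological coefficient of variation was 0.196 over the 5755 genes that passed the expression filter, which held 97.2% of counts.

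The loci that varied most between libraries included ribosomal RNA and a gene opposite to a heat shock gene. By the edgeR quasi-likelihood fit with Benjamini-Hochberg adjustment, 16 genes exceeded the trend. The ribosomal RNA locus CT010467.1 differed 4.84-fold between its highest and lowest library (adjusted p = 1.93e-07 in edgeR) and Gm42418, opposite to it, 7.17-fold (5.03e-29). Ccdc107, opposite to Rmrp, the RNA component of RNase MRP, differed 15.0-fold (1.78e-27), Lars2 9.73-fold (0.00385) and the annotated microRNA Gm23935 3.61-fold (0.00123). These 5 loci were highest in replicate 2. Gm20481, opposite to the heat shock gene Hspa1a, differed 2.97-fold (6.31e-10) and was highest in replicate 4 at 1879 CPM. Zscan10, Gm14966, mt-Co1 and Srpk2 differed by 2.38-fold to 3.04-fold. Zscan10 (217, 211, 502 and 428 CPM in replicates 1 to 4) and Gm47566 (545, 529, 1100 and 829) were lower in replicates 1 and 2, the split seen below at genes of the sex chromosomes, for which the test had no term. Of the 16 loci 5 parted by this split, 9 by replicates 1 and 3 against 2 and 4, and 2 by the third split, against 1684, 2140 and 1931 of the 5755 genes tested. None of the 103 programme list members tested in edgeR passed, also when adjusted over the list alone, and 285 genes of all kinds had an unadjusted p under 0.05. The number past the threshold was 7 without replicate 1, 9 without replicate 2, 10 without replicate 3 and 8 without replicate 4, and 0 with robust fitting. DESeq2 marked 21 dispersion outliers. No programme list had a spread beyond that of matched random lists. The lowest permutation p among 15 lists were 0.0246 for inhibitory receptors, with 3 members tested, and 0.0252 for naive and memory genes (adjusted p = 0.189 for both).

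**Figure D4:**
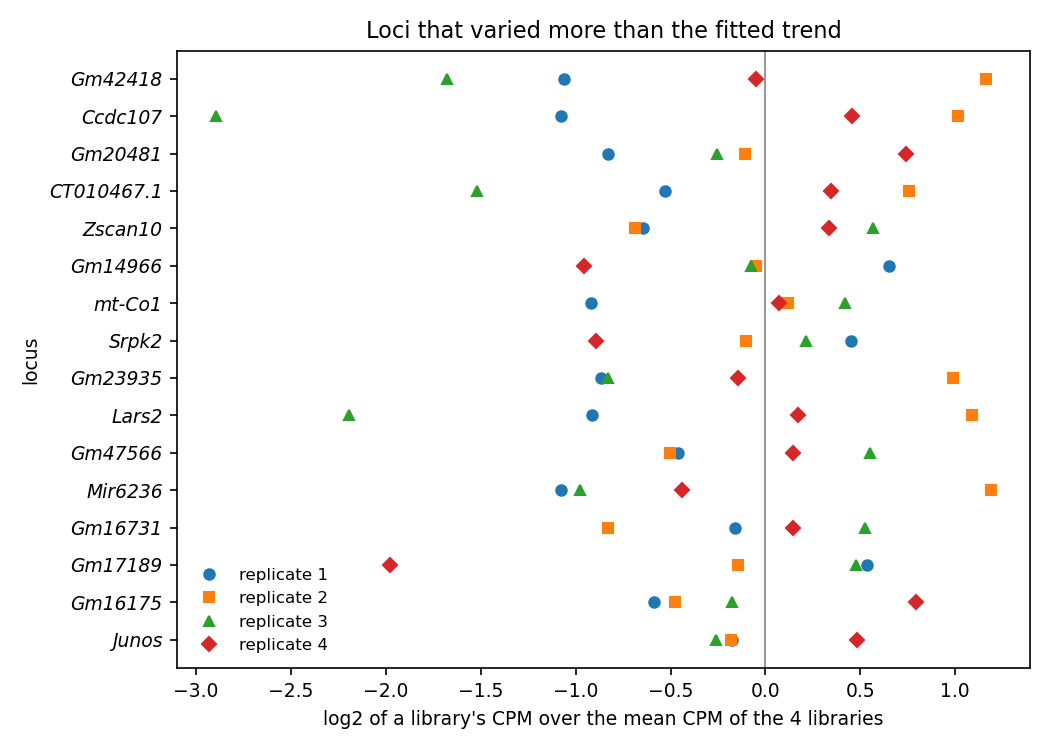
Deviation of each library (symbols) from the mean of the 4 libraries, as log2 of CPM over the mean CPM (x axis), for the 16 loci that varied more than the trend. Replicate 2 was highest at CT010467.1, Gm42418, Ccdc107, Gm23935 and Lars2, and replicate 4 at Gm20481.

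Genes of the sex chromosomes parted the libraries. Tsix, annotated opposite to the X-inactivation RNA Xist, had 3096, 3163, 2 and 1 counts in replicates 1 to 4, and Xist had 77, 192, 0 and 0. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 0, 0, 68 and 23 counts. The expression filter removed these genes from the test of spread, because it requires counts in all 4 libraries.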

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

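All tests of explanations in this part were chosen after the result was seen, except those on genomic DNA and on other genes of chromosome Y. Of 137 values with 4 libraries each, 8 had a library far from the other 3 by Dixon's ratio, and chance gives about 6.85. Replicate 2 stood high for Atf4 (19.1 CPM) and Cd3e (41.2 CPM). Replicate 3 stood high for Aurka (22.9 CPM) and ENSMUSG00000092267 (5742 CPM) and low for Klrk1 (11.4 CPM). Replicate 1 stood low for Gbp2 (4.22 CPM), Skap1 (15.95 CPM) and Trbc1 (15.5 CPM). No explanation was weighed for these genes.

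In the first pattern weighed, most counts lie opposite to another gene. A library that does not keep strand would leave similar densities on both strands, and the 0.417% measured over covered pairs argues against it. Antisense transcripts counted on their own strand would leave ribosomal protein and mitochondrial mRNAs abundant, and ribosomal protein genes with the mitochondrial genes other than mt-Nd6 held 1.21% of counts. A stranded library counted with the opposite setting stays open as a candidate explanation, since mt-Nd6 exceeded the 12 mRNAs of the other mitochondrial strand 14.2-fold. The 12 include neighbouring genes with almost no counts, for a cause that was not tested, which may raise this fold. The library kit is not given in the sources used here, and no other biological explanation was tested.

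In the second pattern, replicate 2 held more counts at genes with no opposite-strand gene within 5 kb, by a median 1.27-fold over 1315 protein-coding genes. The ribosomal RNA locus in the totals is argued against, since replicate 2 had the largest share there (16.8%), which lowers the scaled counts of its other genes. Genomic DNA would raise silent genes as well, and the density at 895 olfactory receptor genes was 9.05% of the excess density. Weaker strand separation in this library stays open. Its ratio of own to opposite density over the covered pairs was 1.49 times the mean of the others. That ratio has own-strand counts as its numerator, and an excess of such counts in replicate 2 is the pattern itself. It was taken over other genes but cannot tell weaker separation from another cause of more own-strand counts. Own and opposite densities were not clearly related over the 193 pairs (Spearman 0.1001, permutation p = 0.172) but were over 166 pairs chosen by the count of the opposite gene alone (0.381, permutation p = 0.0001), which transcripts from both strands could also give, and no biological explanation was tested.

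In the third pattern, genes of the sex chromosomes part the libraries. Cells of mice of different sex stay open as a candidate explanation. The test chosen for it, on 1566 other genes of chromosome Y, found 0 counts in each of the 4 libraries and so decided nothing. The labels give 1 donor identifier and no sex.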

How the results depend on the processing

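The number of assigned fragments limits the low genes, since 3 counts stand for 1.28 to 2.07 CPM. This limit covers fragments on the annotated strand and does not bound transcript levels. The alternatives on opposite-strand neighbours, on shares by strand class and without CT010467.1 and mt-Nd6 were chosen after seeing the data. Alternatives with posterior mean TPM and TPM intervals were not run, nor were any for the 5 ratios without a fold. No comparison between groups was possible because there is 1 group, so differences and ratios were taken within each library. Of 56 alternatives to the 4 list differences, 55 kept the direction, and Th2 minus Th1 was -0.038 over members with no opposite-strand gene within 5 kb. Over members with a TPM of at least 1 in at least 1 library, Th17, Treg and Tfh differences did not keep 1 sign in all libraries. Of 81 alternatives to the 9 ratios, 80 kept the direction, and Il1rl1 over Il23r ranged from -1.70 to 0.53 over the omission of each replicate. None of these tests can pass 0.05, so this says nothing about significance. Genes detected were 13461 when 1 library sufficed and 1260 among genes with no opposite-strand gene within 5 kb, by construction. At 5 TPM, 86 programme members and 8 marker members were detected, against 145 and 17. The share of counts in genes with opposite-strand exon overlap was 87.1% without CT010467.1 and mt-Nd6 and 81.4% among protein-coding genes. The lowest replicate correlation was 0.908 with a pseudocount of 0.1, 0.893 for genes with a TPM of at least 1 in at least 1 library, 0.847 by Spearman, 0.955 for TMM-scaled log2 CPM, 0.832 for genes with no opposite-strand gene within 5 kb, and 0.940 to 0.949 over the omission of each replicate. The biological coefficient of variation was 0.324 without a filter, 0.178 with a mean count of at least 50, 0.241 with DESeq2 dispersions, 0.214 for genes with no opposite-strand gene within 5 kb, and 0.184 to 0.202 over the omission of each replicate. Loci more variable than the trend were 0 with robust fitting, 0 among the 902 genes tested with no opposite-strand gene within 5 kb, and 7 to 10 over the omission of each replicate. By edgeR, 0 lists passed for spread in each alternative that could be run. Where no cause is named, the cause was not tested.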

Other observations

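The tests in this part were all chosen after the counts were seen. Opposite genes had counts beside further list genes. Opposite to Gpi1, a glycolytic enzyme, were 1931 ± 208 CPM (SD, n = 4), against 20.9 ± 2.69 at Gpi1 itself. Opposite to Hif1a, an oxygen-responsive factor, were 542 ± 89.7 CPM, opposite to the kinase gene Tyk2 529 ± 49.9, opposite to Tox 288 ± 8.04 and opposite to the signalling inhibitor Cish 199.5 ± 28.1. Opposite to Slc2a1, a glucose transporter, were 62.4 ± 15.4 CPM and opposite to Plk1, a mitotic kinase, 8.33 ± 3.41. Some list genes had more counts than such an opposite gene. Il16 had 79.6 ± 10.7 CPM against 53.3 ± 10.96, and the hexokinase gene Hk1 had 18.8 ± 4.29 against 6.74 ± 4.44. Foxp3 had 524 ± 28.0 CPM against 0 counts at Gm36995, but it also overlaps Ccdc22, which is protein-coding.

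A hypothesis concerns the state of the cells. The labels name Th2 cells and the file headers name 0 hours. Among members that do not overlap an opposite-strand gene, 5 naive genes stood 3.68 ± 0.13 above 17 activation genes on the log2 scale (SD, n = 4; higher in 4 of 4 libraries; exact sign-flip p = 0.12, the smallest possible). This set left out Cd44 of the naive and memory list, a gene low in these libraries and raised on experienced T cells. With Cd44 kept, 6 genes stood 2.69 ± 0.37 above the activation genes, in 4 of 4 libraries (exact sign-flip p = 0.12). This is consistent with cells taken before activation, but no library of differentiated Th2 cells was analysed here, and the values rest on counts whose strand is open.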
